A study of Sus scrofa with 66 samples.

How the data were processed

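Gene expression was measured in the distal small intestine and the colon of suckling piglets with 2-colour oligonucleotide arrays. Per the labels' protocols, the RNA of each sample was labelled with Cy5 and hybridised against a common pool of 88 samples labelled with Cy3, and no array had the dyes swapped. Samples of the pool without an array among the 66 studied are not analysed here.

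The deposited table holds the authors' normalized log2 ratio of each spot on each array, with 20736 spots and 66 arrays. Per the submitters' processing notes these values came from limma, with no version named. The background correction, the normalization within arrays and the filters on spots are not given in the sources used here. The base of the logarithm and the direction of the ratio are not stated in the table. Base 2 and sample over pool are the likely reading, from the dyes in the labels and from limma's own convention of Cy5 over Cy3. The planned test of the direction used lists of genes of small intestinal absorption and of colonic epithelium. These held 1 and 0 named genes, so it could not be run. In its place, 5 named marker genes of either site could not settle the direction. Of their 15 differences between sites, 10 had the sign the reading needs, and none passed the threshold. If the ratio ran the other way, every higher and lower in the text would swap. If the base differed, every difference would change by 1 common factor and no p-value would change. Array medians lay between -0.01 and 0, so the arrays came centred.

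Of the 20736 spots, 162 had no value on any array and 16092 had a value on all 66. Each array had a value for 18001 to 20311 spots, with a median of 20242. Spot intensities were not analysed here, so signal over background is unknown and the number of arrays sets the precision. The platform annotation paired 178 spots with 1 gene symbol and 0 spots with several, and 20558 spots are unnamed here. The 178 spots name 175 genes, since 4 spots carry ASIP. Current symbols from the reference table of pig genes, assembly Sscrofa11.1, changed 0 of them. That table served for names alone, and no coordinates are given because the spots were not placed on a genome. The 4 ASIP spots were averaged, which left 20733 features. A feature was tested when every group of the fit had at least 3 values, and each feature is a named gene or an unnamed spot.

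Status was taken from the labels, which mark each animal as control or IUGR, the usual abbreviation of intrauterine growth restriction. Before the data were examined, the main fits, the threshold, the rule for naming genes, 34 gene lists and most of the other settings were written down. Each site was fitted alone with 6 groups of age and status in limma 3.58.1 under R 4.3.3, with linear models and empirical Bayes moderation of the variance. A faster version of the same computation was checked against lmFit and eBayes. P-values were adjusted by Benjamini-Hochberg over the features tested, with a threshold of 0.05. Sites were compared through the difference colon minus small intestine within each of the 30 animals with both sites, so that the animal is the replicate. Interactions were tested as contrasts of such differences or with moderated F tests. The test of whether the site difference changes with age and the comparison of sexes were added after the data were seen. Values after the sign ± are standard errors of the fit unless the text says SD.

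Genes were named by a fixed rule. A comparison of status names up to 5 rises and 5 falls past the threshold, or, with fewer than 5 genes past it, the 5 with the smallest p. A comparison of ages or sites names up to 10 rises and 10 falls past the threshold. Genes known only by a LOC number are counted and not named. The 34 lists could not be tested: 18 held at least 1 named gene, the fullest held 3, and the planned minimum was 5. In their place the named genes were sorted into 6 groups, after the annotation and before the values were seen. The groups are cytokines and immune cell genes; antimicrobial and innate defence; digestion, transport and metabolism; hormones, neuropeptides and receptors; genes of other tissues; and structure, growth and protein handling. They were tested against the other named genes with camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were alternatives, and fry tests whether the genes of a group move on balance in 1 direction, without comparing them with other genes.

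The labels give a pair number, and both members of each of the 18 pairs share a birth date in the labels, so the numbers pair the animals. The deviations of the 2 arrays of a pair from their group means were correlated over features. In the colon the median correlation was 0.224 over 15 pairs, with a range from -0.515 to 0.718 and 9 pairs over 0.1, against -0.0238 for arrays of different pairs. Because deviations from a group mean cancel within the group, the value for different pairs is tied to that within pairs. It is thus no independent baseline. In the small intestine the median was -0.0424 over 18 pairs, with a range from -0.482 to 0.361 and 5 pairs over 0.1. Fits with the pair as a block were alternatives, and each pair has 1 age.

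Each fit was tested on simulated data with known changes, once with independent noise and once with the real residuals of shuffled arrays, which keep the correlation between features. In the status fits given here, 66 or 67 features each were changed by 0.25, 0.5 and 1 at the same time. The adjustment is stricter when fewer features change, so the shares recovered would be lower for a few changed features. With independent noise, changes of 0.5 on the log2 scale were recovered in 88.1% of cases for status in the small intestine at day 0 and in 91.0% at day 5. In the colon the share was 68.7% at day 0, 65.7% at day 2 and 59.7% at day 5. With real residuals those shares were 83.6% and 88.1% in the small intestine and 60.6%, 58.2% and 50.7% in the colon. Changes of 1 were recovered in 98.5% to 100% of cases in those 5 fits with independent noise, and in 97.0%, 98.5%, 97.0%, 97.0% and 86.4% with real residuals. With a change of 0.25 the share was 34.3% for the small intestine at day 0 and 8.96% for the colon at day 0 with independent noise, and 31.3% and 4.48% with real residuals. The status by age interaction recovered fewer changes of 0.5. The share was 58.2% in the small intestine and 10.4% in the colon with independent noise, and 49.3% and 18.2% with real residuals. For status in the small intestine at day 5 the simulation with real residuals gave 306 false calls, against 7 with independent noise.

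The alternatives were scaling of the arrays to a common spread, quantile normalization, array weights, complete features only and spots tested singly. Fits of the compared groups alone, robust moderation, and thresholds of 0.01 and 0.1 were also run. Further alternatives were sex as a covariate for status, pair blocks, 1 status group at a time for ages, and all arrays with the animal as a random block for sites. Each array or animal of the compared ages was left out in turn, while those of other ages in the same fit were kept. Added after the data were seen were the omission of the array with the widest log ratios, of the array with the most empty spots and of 288 spots at the ends of the 48 printing blocks, and 2 principal components as covariates. For each count of features, up to 100 splits of the animals into groups of the same sizes, the real one included, were drawn with a fixed seed. For the counts between the sites, a split instead swapped the colon and small intestine labels in a random subset of the animals of that age. Body weights from the labels were compared within each age by an exact two-sided permutation test over 924 permutations, with adjustment over 6 tests. The same differences were tested within pairs by an exact two-sided sign-flip test, added after the data were seen.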

Results

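The time course followed suckling piglets killed at 0, 2 or 5 days of age, with the aim, from the series title, of describing how the intestine responds after birth to IUGR. The 36 animals formed 18 pairs of 1 control and 1 IUGR piglet, with 6 animals per status at each age. The distal small intestine was studied in all 36 and the colon in 30, which gave 6 arrays per group for the small intestine and 5 per group for the colon. Each array reported the log2 ratio of 1 sample to a common pool for 18001 to 20311 spots. The median absolute deviation of the log ratios of an array was 0.24 in the median array and ranged from 0.18 to 0.54. Across the 16089 features with a value on all arrays, the correlation between 2 arrays had a median of 0.741 and ranged from 0.165 to 0.941, and 0 pairs of arrays were identical. Arrays of 1 group correlated at 0.737 on average, arrays of 1 site at 0.727, and the 2 sites of 1 animal at 0.725. Arrays of different sites and animals correlated at 0.695, so most of this correlation was common to all arrays. Gene names were at hand for 175 genes, so most calls below belong to unnamed spots. Higher and lower are given for sample over pool, the likely direction of the ratio, and would swap if it ran the other way.

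Body weight showed what the status labels stand for. At birth the IUGR piglets weighed 0.910 ± 0.0865 (SD, n = 6) in the day 0 group against 1.36 ± 0.0473 in controls, in the unit of the labels, which is not stated. The values were 0.937 ± 0.0320 against 1.38 ± 0.0388 in the day 2 group and 0.903 ± 0.103 against 1.41 ± 0.0589 in the day 5 group. IUGR birth weight was thus 66.9%, 68.0% and 63.9% of control, and the exact permutation p of 0.00216 at each age, the smallest these groups can give, became 0.00433 after adjustment. At each age every IUGR piglet weighed less at birth than every control. If the animals were given their status by birth weight, the outcome of these birth weight tests was fixed by that choice. By day 2 the IUGR piglets had gained 0.05 ± 0.0892 and the controls 0.217 ± 0.0814 (SD, n = 6; exact permutation p = 0.0152, adjusted 0.0227). By day 5 the gains were 0.357 ± 0.312 and 0.588 ± 0.352, which did not pass the test (n = 6; exact permutation p = 0.253, adjusted 0.304). Within pairs, IUGR birth weight was lower in 6 of 6 pairs at each age. The exact sign-flip p was 0.0312, the smallest that 6 pairs can give, and 0.0625 after adjustment over the 6 tests. In both adjustments 1 of the 6 tests was gain at day 0, which was 0 in every animal, so its outcome was fixed. The day 2 gain was lower in 5 of 6 pairs and equal in 1, and did not pass within pairs (exact sign-flip p = 0.0625, adjusted 0.0938).

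IUGR was compared with control in the small intestine at each age, the central question of the series. At day 5 the smallest p-values among named genes belonged to GNAS, the alpha subunit of the stimulatory G protein, with a log2 difference of -0.30 ± 0.086 (adjusted p = 0.332), and IVL, the cornified envelope protein involucrin, with -0.26 ± 0.078. GAD1, which makes the transmitter GABA, had 0.21 ± 0.066, the cone arrestin ARR3 had -0.33 ± 0.12 and the melanosome protein OCA2 had 0.21 ± 0.081. At day 0 they were MBL2, a lectin of innate immunity (0.25 ± 0.096), MMP14, a membrane-bound matrix protease (-0.10 ± 0.040), RPN2 of the glycosylation machinery (-0.19 ± 0.076), B3GALNT1 (-0.14 ± 0.060) and the cell cycle inhibitor CDKN2B (0.26 ± 0.12). At day 2 they were the organic cation transporter SLC22A2 (0.19 ± 0.064), the agouti gene ASIP (0.14 ± 0.063), LHB (0.15 ± 0.077), the transcription factor GATA6 (-0.14 ± 0.077) and the hormone precursor POMC (-0.10 ± 0.057). None of these 15 genes passed the threshold, and the groups held 6 animals each.

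With limma, 0 of 19798 features in the small intestine had an adjusted p under 0.05 at day 0, day 2 or day 5. At an unadjusted p under 0.05 there were 704, 388 and 2160 features, where 989.9 are expected by chance, and the lowest adjusted p at day 5 was 0.0874. The count of 0 at day 5 rested on both of 2 IUGR arrays: it became 12 without that of pair 20 and 2 without that of pair 22. Over the 3 ages together, 18 animals against 18, the count was 0 with 867 at an unadjusted p under 0.05, and the named genes with the smallest p were ASIP (0.10 ± 0.036), GNAS (-0.13 ± 0.049), the placental glycoprotein PAG6 (0.22 ± 0.093), LHB (0.10 ± 0.044) and the heart hormone NPPA (0.09, adjusted p = 0.989). The test of whether the status difference changed with age called 0 features, with 1052 at an unadjusted p under 0.05 and 1 without the IUGR array of pair 5 at day 0. Its smallest p-values were those of IVL, MMP14, OCA2, GNAS and ARR3, each with an adjusted p of 0.880. In the simulations this test missed many changes of 0.5, with 58.2% recovered with independent noise and 49.3% with real residuals. The median 95% confidence interval of a status difference reached 0.15 to either side at each age and 0.09 over the 3 ages, on the log2 scale.

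In the colon the same comparison rested on 5 animals against 5. The named genes with the smallest p at day 0 were IVL (-0.21 ± 0.099), the histamine receptor HRH4 (-0.30 ± 0.15), the T cell cytokine IL17A (-0.33 ± 0.16), ARR3 (-0.21 ± 0.11) and KLF4, a transcription factor of differentiating epithelium (0.08 ± 0.053). At day 2 they were the inhibin subunit INHA (-0.34 ± 0.14), KLF4 (0.12 ± 0.053), the serotonin receptor HTR1F (0.16 ± 0.075), ARR3 (-0.23 ± 0.11) and ATP5G1 of the mitochondrial ATP synthase (0.33 ± 0.17). At day 5 they were HRH4 (0.35 ± 0.15), the neuropeptide PACAP encoded by ADCYAP1 (-0.40 ± 0.18), the steroid hydroxylase CYP21A2 (-0.29 ± 0.15), the macrophage lectin SIGLEC1 (0.18 ± 0.10) and HTR1F (-0.14 ± 0.075). None of them passed the threshold. Limma called 0 of 19743 features at day 0, day 2 and day 5, with 192, 452 and 332 at an unadjusted p under 0.05 against 987.15 expected by chance. Over the 3 ages it called 0, with 422 at an unadjusted p under 0.05, and the genes were KLF4 (0.07 ± 0.031), the calcium-binding protein S100A11 (0.08 ± 0.042), IL17A (-0.18 ± 0.092), PI3 (0.13 ± 0.070) and the receptor FSHR (0.16 ± 0.084). The interaction with age called 0, with 173 at an unadjusted p under 0.05, and HRH4, HTR1F, PGLYRP1, UTS2 and ARR3 had its smallest p (adjusted p = 1.00). In the simulations this interaction test recovered 10.4% of changes of 0.5 with independent noise and 18.2% with real residuals. Its count of 0 thus says little about changes of that size. The median 95% confidence interval of a status difference reached 0.23 to either side at day 0.

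Whether the response to IUGR differed between the sites was tested within the 30 animals. CDKN2B (-0.22 ± 0.083), IL17A (-0.32 ± 0.12), ADCYAP1 (-0.19 ± 0.084), SLC22A2 (-0.13 ± 0.063) and LAMP1 (-0.14 ± 0.070) had the smallest p, as the IUGR minus control difference in the colon less that in the small intestine. None passed the threshold: limma called 0 of 19604 features, with 582 at an unadjusted p under 0.05. None of the 6 groups of named genes passed in any comparison of status by camera. The nearest in the small intestine at day 5 was antimicrobial and innate defence, 12 genes with 2 above 0 and a median of -0.07 (adjusted p = 0.127).

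With age, the small intestine changed in both directions while both status groups were averaged, 12 animals per age. PI3, the elastase inhibitor elafin of mucosal defence (spot 18964), rose from a mean log2 ratio of -0.58 ± 0.25 (SD, n = 12) at day 0 to -0.11 ± 0.40 at day 2 and 0.22 ± 0.34 at day 5. LAMP1, a glycoprotein of the lysosomal membrane (spot 6004), fell from 0.57 ± 0.16 to 0.34 ± 0.20 and 0.22 ± 0.12. Between day 0 and day 5 the change was 0.80 ± 0.13 for PI3, a 1.74-fold rise (adjusted p = 0.000371), and -0.35 ± 0.065 for LAMP1 (adjusted p = 0.00157). JUN, a subunit of the transcription factor AP-1, fell by 0.18 ± 0.037 (adjusted p = 0.00887) and SIGLEC1 rose by 0.19 ± 0.049 (adjusted p = 0.0320). The leptin receptor LEPR rose by 0.36 ± 0.079 from day 0 to day 2 (adjusted p = 0.0340), and its change from day 0 to day 5 was 0.23 ± 0.079 (adjusted p = 0.189).

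**Figure D1:**
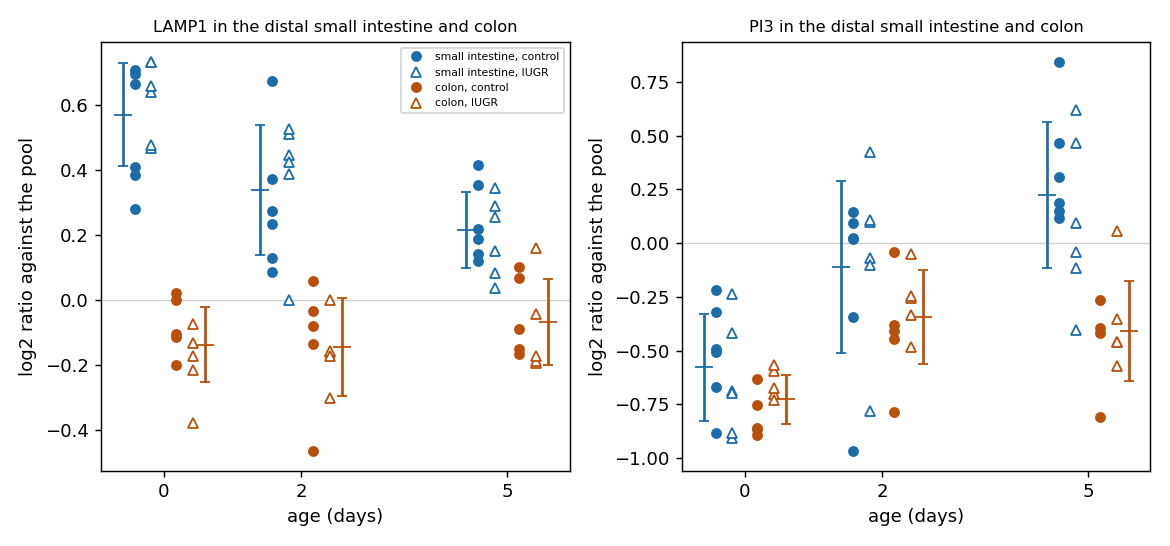
Log2 ratio against the pool of LAMP1 (left) and PI3 (right) by age in days, with 1 point per array for control (filled) and IUGR (open) animals, and bars with whiskers for the mean and SD over both status groups. In the small intestine the LAMP1 mean lay at 0.57, 0.34 and 0.22 and the PI3 mean at -0.58, -0.11 and 0.22, while in the colon the LAMP1 mean lay at -0.14, -0.14 and -0.07.

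Limma called 253 of 19798 features between day 0 and day 5 of the small intestine, 150 higher and 103 lower at day 5. Between day 0 and day 2 it called 34, 28 higher and 6 lower, and between day 2 and day 5 it called 3, all 3 higher. Among unnamed spots, spot 980 rose by 1.30 ± 0.15 and spot 3057 by 1.19 ± 0.14 by day 5 (adjusted p = 3.35e-06 for each), and spot 18739 fell by 0.69 ± 0.13 (adjusted p = 0.00216). Of 12 antimicrobial and innate defence genes, PI3 rose, the other 11 did not pass, and 8 had a positive value. As a group they had a median of 0.06 and did not pass with camera (adjusted p = 0.0512, and adjusted p = 0.150 with an estimated correlation), but did under quantile normalization (adjusted p = 0.0204). Of 40 genes of structure, growth and protein handling, LAMP1 and JUN fell and 14 had a positive value (camera adjusted p = 0.139).

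PI3, LAMP1 and JUN kept their calls in each of the 24 fits that left out 1 array of the small intestine. SIGLEC1 lost its call in 11 of them, with an adjusted p up to 0.0760, and these left out control pairs 1 and 15 and IUGR pairs 1, 13 and 14 of day 0 and control pairs 19, 22 and 24 and IUGR pairs 19, 20 and 22 of day 5. LEPR lost its call in 12, with an adjusted p up to 0.0964, and these left out control pairs 1, 6 and 15 and IUGR pairs 5, 6 and 14 of day 0 and control pairs 7, 8 and 17 and IUGR pairs 2, 16 and 17 of day 2. The count of 253 became 163 without control pair 1 of day 0. The count of 34 became 17, 20 and 89 without control pairs 17, 8 and 2 of day 2, 21 without IUGR pair 16 of day 2 and 22 without control pair 6 of day 0. The count of 3 became 5 without control pair 16 of day 2. It became 1 without control pairs 2 and 18 or IUGR pairs 2, 7 and 16 of day 2, or control pairs 10 and 22 or IUGR pairs 19 and 22 of day 5. With animals of 1 status alone, 6 per age, PI3 changed by 0.86 in controls and 0.74 in IUGR animals and passed in controls alone (adjusted p = 0.198 in IUGR animals). LAMP1 changed by -0.28 in controls and -0.42 in IUGR animals and passed in IUGR animals alone (adjusted p = 0.207 in controls). Each change thus had the same sign in both status groups, and JUN, SIGLEC1 and LEPR passed in neither. The SIGLEC1 change was 0.29 in controls and 0.10 in IUGR animals.

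In the colon, RXFP4, the receptor of the gut hormone insulin-like peptide 5, rose by 0.30 ± 0.069 from day 0 to day 5 (adjusted p = 0.0397; 10 animals per age). TMPRSS15, the enteropeptidase that activates trypsinogen, fell by 0.23 ± 0.056 (adjusted p = 0.0435). PI3 had a change of 0.31 ± 0.087 (adjusted p = 0.0568) and LAMP1 one of 0.07 ± 0.063 (adjusted p = 0.508), and neither passed. Limma called 319 of 19743 features between day 0 and day 5, 104 higher and 215 lower, with 73 when the pair entered as a random block. TMPRSS15 then had an adjusted p of 0.0543, and with 2 components as covariates its change was -0.14 (adjusted p = 0.434). Between day 0 and day 2 it called 3, all 3 higher and all unnamed, and between day 2 and day 5 it called 0, with 1113 at an unadjusted p under 0.05. None of the 6 gene groups passed with camera in the colon. Of the calls between day 0 and day 5, 1 feature was higher in both sites where 0.791 are expected of independent lists, 2 were lower in both where 1.12 are expected, and 1 went opposite ways. These lists share their animals.

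The colon counts depended on single arrays. Without control arrays of day 5 the count of 319 became 16 (pair 9), 38 (pair 24), 42 (pair 19) and 948 (pair 10), and without IUGR arrays of day 5 it became 26 (pair 24), 34 (pair 10), 46 (pair 19), 595 (pair 9) and 2047 (pair 22). Without control arrays of day 0 it became 34 (pair 6), 49 (pair 5), 55 (pair 13), 67 (pair 14) and 90 (pair 1), and without IUGR arrays of day 0 it became 29 (pair 6), 48 (pair 14), 53 (pair 5) and 135 (pair 13). The IUGR array of pair 17 of day 2, the widest, is outside the compared ages but in the same fit. Without it the count was higher than with any of these omissions. Quantile normalization gave 1210 calls and 2 principal components as covariates gave 11. The balance of 104 higher and 215 lower turned to 382 and 333 with array weights, 285 and 245 with the compared groups alone and 11 and 0 with 2 components. RXFP4 lost its call in 12 of 20 such fits, with an adjusted p up to 0.0895, which left out control pairs 1, 5, 6 and 14 and IUGR pairs 5 and 6 of day 0 and control pairs 9, 19 and 24 and IUGR pairs 10, 19 and 24 of day 5. TMPRSS15 lost its call in 15 of 20, with an adjusted p up to 0.0907, which left out all of those and control pair 13 and IUGR pairs 13 and 14 of day 0. The 3 calls between day 0 and day 2 became 1 without control pairs 5 and 14 of day 0, control pair 16 of day 2 or IUGR pair 7 of day 2. They became 5 without control pair 6 of day 0 or control pair 17 of day 2 and 10 without IUGR pair 17 of day 2. Without that last array, the 0 calls between day 2 and day 5 became 1.

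The 2 sites of the same animal were compared to ask which transcripts mark the colon against the distal small intestine at each age. LAMP1 was lower in the colon at all 3 ages, by a log2 difference of -0.69 ± 0.061 at day 0 (adjusted p = 4.43e-08; lower in 10 of 10 animals), -0.52 ± 0.061 at day 2 (adjusted p = 2.82e-06; 10 of 10) and -0.26 ± 0.061 at day 5 (adjusted p = 0.0115; 9 of 10). PI3 was lower in the colon at day 5 (-0.65 ± 0.13, adjusted p = 0.00439; lower in 8 of 9 animals with both values), with values of -0.14 ± 0.13 at day 0 and -0.23 ± 0.13 at day 2 that did not pass. The colon level of LAMP1 was -0.14 ± 0.12 at day 0, -0.14 ± 0.15 at day 2 and -0.07 ± 0.13 at day 5 (SD, n = 10). Whether the LAMP1 site difference changed with age was tested itself and did not pass over all features (moderated F test, adjusted p = 0.0588).

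At day 0, PGK2, a phosphoglycerate kinase known from testis, was also lower in the colon (-0.31 ± 0.066, adjusted p = 0.0188; 10 of 10 animals). At day 2 the colon was higher for the calcitonin receptor-stimulating peptide CRSP3 (0.33, adjusted p = 0.0188), the beta-defensin DEFB110 (0.30, adjusted p = 0.0331) and the lipid droplet protein PLIN1 (0.16, adjusted p = 0.0391), each in 9 of 10 animals. At day 5 genes of cytokines and immune cells went both ways. IFN-DELTA-1, a type I interferon (0.46 ± 0.091, adjusted p = 0.00290; higher in 10 of 10), the cytokine LIF (0.54, adjusted p = 0.0201; 9 of 10) and the OX40 ligand TNFSF4 (0.39, adjusted p = 0.0325; 9 of 10) were higher in the colon. The death receptor FAS (-0.47, adjusted p = 0.0104; 9 of 10) and the T cell cytokine IL21 (-0.26, adjusted p = 0.0463; 7 of 9) were lower. With 2 components as covariates the differences shrank to 0.34 for LIF (adjusted p = 0.00329), 0.23 for TNFSF4 (adjusted p = 0.0816) and -0.29 for FAS (adjusted p = 0.00707). JUN was higher (0.19, adjusted p = 0.0235; 9 of 10), as was CRSP3 (0.25, adjusted p = 0.0488; 8 of 10), and TMPRSS15 was lower (-0.19, adjusted p = 0.0204; 9 of 10). By camera none of the 6 gene groups shifted between the sites at any age.

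Limma called 194 of 19604 features between the sites at day 0, 39 higher and 155 lower in the colon. It called 541 at day 2, 206 higher and 335 lower, and 1801 at day 5, 847 higher and 954 lower. The balance of higher and lower turned with the setting: it was 364 and 345 at day 2 and 957 and 709 at day 5 with scaling, 392 and 347 and 922 and 798 with quantile normalization, and 640 and 328 at day 0, 1307 and 865 at day 2 and 766 and 463 at day 5 with 2 components as covariates. At day 5 it also turned with array weights (1035 and 986). Fits of the compared groups alone called 212 at day 0, 103 at day 2 and 239 at day 5 (138 higher and 101 lower). Lists of different ages came from different animals, but each feature had 1 spread estimated over all ages, so the lists were not independent. At both day 0 and day 2, 19 features were higher in the colon where 0.410 are expected of independent lists. Of lower features 77 were shared where 2.65 are expected. At both day 2 and day 5, 86 were higher where 8.90 are expected and 115 were lower where 16.3 are expected, and 0 of these shared calls changed direction. The largest unnamed difference at day 0 was at spot 18739, with -1.74 ± 0.10 (adjusted p = 9.39e-12), and -1.22 ± 0.11 at day 5. A moderated F test of whether the site difference changed with age called 24 features, none of them named, and 45 with the pair as a random block.

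LAMP1 at each age and PI3, IFN-DELTA-1 and FAS at day 5 kept their calls when any of the 10 animals of an age was left out. In fits of the compared groups alone, however, PI3 was the only named gene to keep its call at day 5. The PGK2 call was lost without control pair 1 or IUGR pairs 5 or 14 (adjusted p up to 0.0851). At day 2, CRSP3 lost its call without IUGR pair 17 or control pair 7 (up to 0.0712), DEFB110 without either animal of pairs 2 and 7, control pairs 16 and 18 or IUGR pair 17 (up to 0.128), and PLIN1 without either animal of pair 7, control pairs 2, 16 and 18 or IUGR pair 17 (up to 0.132). At day 5, control pair 19 and IUGR pair 10 each decided the calls of LIF (adjusted p up to 0.0947) and TMPRSS15 (up to 0.0888), and control pair 19 and IUGR pair 24 that of JUN (up to 0.0633, with a difference of 0.12 without IUGR pair 24). TNFSF4 lost its call without control pairs 19, 22 and 24 or IUGR pairs 9 and 10 (up to 0.148), CRSP3 without either animal of pairs 9 and 24, control pair 19 or IUGR pair 10 (up to 0.158), and IL21 without either animal of pairs 9, 10 and 24 or control pairs 19 and 22 (up to 0.171).

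The counts between sites also moved with single animals. At day 0 the 194 became 104 without control pair 1 and 129 without IUGR pair 5. At day 2 the 541 became 306 and 352 without control pairs 18 and 16, 344 without IUGR pair 17 and 1090 without IUGR pair 16. At day 5 the 1801 became 463, 1096 and 3654 without IUGR pairs 10, 9 and 22, and 839, 971, 1018 and 1161 without control pairs 19, 24, 9 and 22. The 24 features of the F test became 5 without control pair 1 of day 0, 6 without IUGR pair 1 of day 0, 8 without control pair 24 of day 5, 146 without IUGR pair 22 of day 5 and 159 without IUGR pair 17 of day 2. They became 15 without IUGR pair 13 or control pair 5 of day 0 or control pair 10 of day 5.

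**Figure D2:**
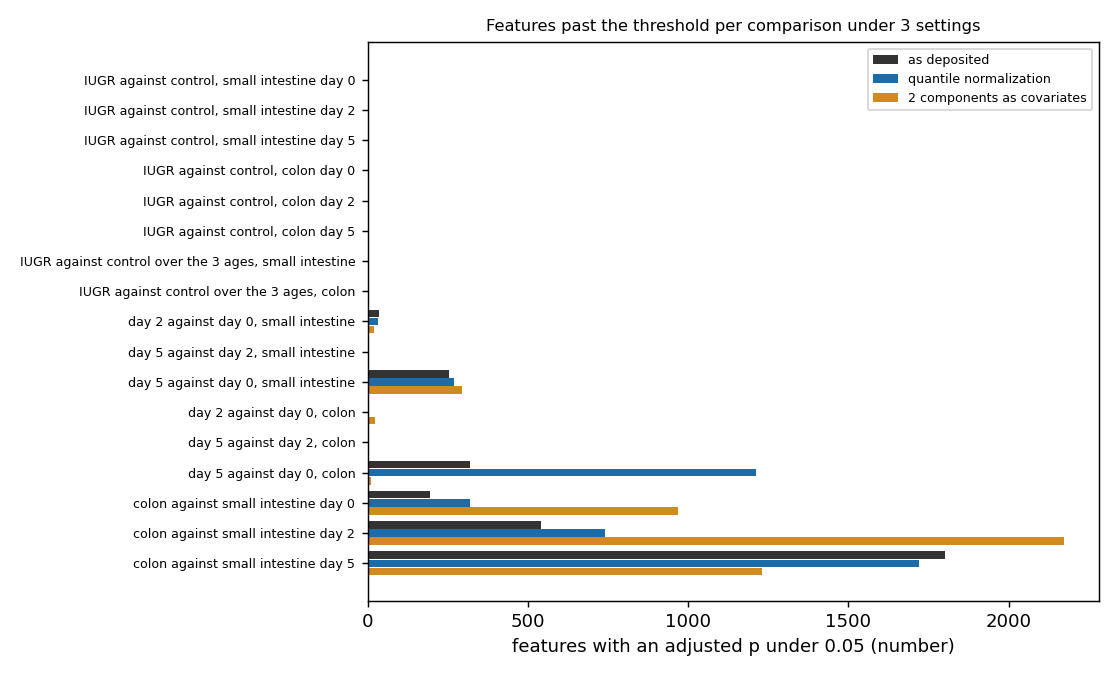
Number of features past the threshold (horizontal axis, adjusted p under 0.05) in each comparison of status, age and site, with 1 bar per setting: values as deposited, quantile normalization, and 2 principal components as covariates. The 8 status comparisons stay at 0 under all 3 settings, while the bar for day 5 against day 0 in the colon runs from 11 to 1210 and that for the sites at day 0 from 194 to 968.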

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

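The test of the site difference by age, its splits and the counts with principal components as covariates for the colon and for the sites were chosen after the results were seen. The real split is counted among the splits below, so 1 of 100 means that no other split gave as many.

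At day 5 the small intestine of IUGR and control piglets differed at an unadjusted p under 0.05 in 2160 features, against 989.9 expected by chance, although 0 passed limma's adjusted threshold. Of 100 splits of the animals 10 gave as many, the highest other 4066, so chance cannot be excluded. Sex as a covariate left 2242 features, which argues against the excess of males among the IUGR piglets as the whole cause. With 2 principal components as covariates 1174 were left, so variation shared by whole arrays is a candidate explanation. The group means were not removed before the components were taken, so this fit could also remove a status difference. Over all small intestine arrays the components correlate with status at 0.115 and 0.0935 in size. A weak response to IUGR stays open, and without the IUGR arrays of pairs 20 and 22 the adjusted count became 12 and 2.

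In the colon 319 features differed between day 5 and day 0. Of 100 splits of the animals 2 gave as many, the highest other 357. Of 100 splits that kept pairs together 3 did, the highest other 524. So large a count was thus uncommon among the splits, but other splits exceeded it, so chance is not excluded. Of the sum of squares of the called changes, over the 281 of 319 features with a value on all arrays, a share of 0.618 lay along the first 2 components of the variation within groups, and over all features it was 0.671, against 0.0143 and 0.114 in the small intestine. With 2 components as covariates the count was 11. In the colon these components also correlate with age, at 0.436 and 0.340 in size, and with sex, at 0.326 and 0.407. Variation shared by whole arrays may therefore account for much of the count. A change of the colon with age stays open, and no comparison of ages was fitted with sex as a covariate.

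The number of calls between the sites rose with age, from 194 at day 0 to 541 at day 2 and 1801 at day 5, and 24 features had a site difference that itself changed with age. Of 100 splits 1, 1 and 2 gave as many calls at day 0, day 2 and day 5, the highest others 83, 115 and 2823. For the 24 features 1 of 100 gave as many, the highest other 1. With pairs kept together 1 of 16 splits gave as many calls at each age, the highest others 1, 1 and 416. So few splits cannot give a share under 0.05. As many calls were thus rare among the 100 splits, but at day 5 another split exceeded the real count, so chance is not excluded there. In fits of the compared groups alone the counts were 212, 103 and 239, so most of the rise went with that setting, and the day 5 count became 463 without the IUGR animal of pair 10 and 3654 without that of pair 22. Of the sum of squares of the genes called at day 5, over the 1508 with a value on all arrays, a share of 0.612 lay along the first 2 components within groups (0.575 over all features), so variation shared by whole arrays is a candidate explanation for part of that count, but the first component also correlates with age and with sex, at 0.417 and 0.455 in size. With 2 components as covariates the counts were 968, 2172 and 1229 and the ratio of day 5 to day 0 calls fell from 9.28 to 1.27, mainly because day 0 rose, which does not decide the cause, and the test of a site difference that changes with age called 38 features, so such a change stays open.

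For the other counts the splits read as follows. In the small intestine 1 of 100 splits gave as many features as the 34 between day 0 and day 2 (highest other 1). For the 253 between day 0 and day 5 it was also 1 of 100 (119), so no other split reached either count. For the 3 between day 2 and day 5, 4 of 100 did (624), without adjustment over the counts tested, so chance cannot be excluded. Nor can it be excluded for the counts at an unadjusted p under 0.05. There 13 of 100 gave as many as the 1841 between day 0 and day 2 (highest other 3822). For the 1686 between day 2 and day 5, 14 did (5311), and for the 2163 between day 0 and day 5, 7 did (3577). In the colon 1 of 100 gave as many as the 3 between day 0 and day 2 (highest other 0), and 3 of 100 splits that kept pairs together did (150). For the status comparisons, both interactions with age, the interaction with site and day 2 against day 5 in the colon, the real count was 0, which 100 of 100 splits reach by definition, so the splits say nothing about chance there. Some splits called many features, which points to a structure of the samples or to noise shared between features, and which of these applies was not tested. In 1 simulation with real residuals of shuffled arrays, status in the small intestine at day 5 gave 306 false calls. Among the comparisons with a real count of 0, the highest counts of the splits were 1256 for status in the small intestine at day 2, 1786 in the colon at day 5, 188 in the colon at day 0, 169 in the colon over the 3 ages, 15 in the small intestine at day 5 and 1824 between day 2 and day 5 in the colon. In the splits that part every pair as the real one does, the highest counts were 266 for status in the small intestine at day 2, 320 for status in the small intestine over the 3 ages, 548 for the interaction with site, 13 for that with age in the colon and 12 for status in the colon at day 2.

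Samples far from the others of their group were found in 19 of 226 groups tested, where 11.3 are expected by chance. Empty spots numbered 1370 on the colon day 0 control array of pair 13, 2735 on the colon day 5 control array of pair 19, 1158 on the colon day 5 IUGR array of pair 22 and 920 on the small intestine day 5 IUGR array of pair 20. The median absolute deviation was 0.54 on the colon day 2 IUGR array of pair 17, which also stood apart for LIF at 1.98 and TNFSF4 at 1.84. The colon day 5 IUGR array of pair 24 stood apart for IFN-DELTA-1 at 1.29 and JUN at 0.55, and the small intestine array of the same animal for LIF at 0.66. JUN was at -0.37 on the colon day 2 control array of pair 17, and RXFP4 was at -0.48 on the colon day 5 IUGR array of pair 22. In the small intestine, LAMP1 was at 0.00063 on the day 2 IUGR array of pair 8, and TNFSF4 was at 0.10 on the day 5 control array of pair 22. At day 0 of the small intestine, DEFB110 was at -0.16 on the control array of pair 15 and at -0.13 on the IUGR array of pair 5, and PGK2 was at 0.46 on that same IUGR array. Also at day 0, LIF was at -0.16 on the IUGR array of pair 14 and SIGLEC1 was at 0.60 on the control array of pair 13.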

How the results depend on the processing

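The omission of the array with the widest log ratios, of the array with the most empty spots and of the spots at block ends, the 2 principal components as covariates, the site by age test and the paired test of body weight were chosen after the data were seen. The groups of named genes were written after the annotation and before the values were seen. Called genes named in the text kept their sign under every setting run, and other called features were not followed singly. The counts for status were 0 in both sites at each age, over the ages and for the 3 interactions. They stayed at 0 with the pair as a fixed replicate block and with sex as a covariate. With both they also did, a fit not run for the interaction with site. At day 2 no control was male, so sex was adjusted there only through IUGR animals and other ages. Apart from fits without 1 array, only array weights and a threshold of 0.1 gave calls. These were 1 feature at day 0 of the small intestine and 10 at its day 5 (9 higher and 1 lower), respectively. The paired block changed 2 counts and 1 gene: 319 to 73 for day 5 against day 0 in the colon, where TMPRSS15 lost its call, and 24 to 45 for the site by age test. For body weight the test within pairs kept the differences of -0.45, -0.44 and -0.51 in birth weight at day 0, day 2 and day 5. It also kept that of -0.167 in gain at day 2. All 4 calls were lost after adjustment (exact sign-flip test, adjusted p = 0.0625 for birth weight and 0.0938 for gain). For birth weight this reflects the setup: 6 pairs allow no p under 0.0312, and each birth weight test had that value. Gain at day 0, 0 in every animal, was also among the 6 tests. The paired block changed no other call.

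For day 2 against day 0 in the small intestine, the count of 34 became 84 with array weights, 15 and 65 with thresholds of 0.01 and 0.1, 0 in control and 1 in IUGR animals alone, and 18 with 2 components. Its higher and lower calls were 28 and 6, and 23 and 10 under quantile normalization. For day 5 against day 2, the 3 became 6 with array weights, 1 with the compared groups alone and with a threshold of 0.01, and 0 in either status group alone. For day 5 against day 0, the 253 became 527 with array weights, 103 and 395 with thresholds of 0.01 and 0.1, and 49 and 32 in control and IUGR animals alone.

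For day 2 against day 0 in the colon, the 3 became 359 with array weights, 1 and 7 with thresholds of 0.01 and 0.1, 0 in either status group alone, 10 without the widest array and 22 with 2 components. For day 5 against day 2, the 0 became 4 with array weights and 1 without the widest array. The widest array was the IUGR array of pair 17 at day 2, which is also in the fit of day 5 against day 0. For day 5 against day 0, the 319 became 1203 with scaling, 1210 with quantile normalization, 715 with array weights, 530 with the compared groups alone, 6 and 1829 with thresholds of 0.01 and 0.1, 1 and 0 in control and IUGR animals alone, 2118 without the widest array, 42 without the array with the most empty spots and 11 with 2 components.

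Between the sites at day 0, the 194 became 337 with scaling (108 higher and 229 lower), 318 with quantile normalization (93 and 225), 402 with array weights, 100 and 298 with thresholds of 0.01 and 0.1, and 968 with 2 components (640 higher and 328 lower, against 39 and 155). At day 2, the 541 became 103 with the compared groups alone, 194 and 1256 with thresholds of 0.01 and 0.1, 344 without the widest array and 2172 with 2 components (1307 and 865, against 206 and 335), and its split was 364 and 345 with scaling and 392 and 347 with quantile normalization. At day 5, the 1801 became 239 with the compared groups alone, 345 and 3407 with thresholds of 0.01 and 0.1, 3024 without the widest array and 839 without the array with the most empty spots, and its split was 957 and 709 with scaling and 922 and 798 with quantile normalization. The 24 of the site by age test became 80 with scaling, 62 with quantile normalization, 203 with array weights, 15 with complete features only, 5 and 128 with thresholds of 0.01 and 0.1, 159 without the widest array and 38 with 2 components. The 0 gene groups of 108 tests became 2 with fry, which tests whether a group moves on balance in 1 direction and is thus a different comparison from that with the other named genes (structure, growth and protein handling between day 2 and day 5 of the small intestine, adjusted p = 0.0399; genes of other tissues between day 2 and day 5 of the colon, adjusted p = 0.0141) and 1 with quantile normalization. Camera with an estimated correlation gave 0. Thresholds and smaller groups change counts by construction, and for the other settings the cause was not tested.

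Leaving out 1 array or animal of the compared ages at a time gave 0 to 12 features for status at day 5 of the small intestine. It gave 0 to 1 for the status by age interaction there. The range was 17 to 89 for day 2 against day 0, 1 to 5 for day 5 against day 2 and 163 to 320 for day 5 against day 0 in the small intestine. In the colon it was 1 to 10, 0 to 1 and 16 to 2047 for the same comparisons. The widest array, of day 2, was outside the last of these, and the count without it lay above this range. Between the sites it was 104 to 176 at day 0, 306 to 1090 at day 2 and 463 to 3654 at day 5, and 5 to 159 for the site by age test.

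Among named genes, LAMP1 kept its call between the sites in 15 of 15 settings at day 0 and at day 2 and in 13 of 15 at day 5, and PI3 did in 14 of 14 at day 5. For day 5 against day 0 in the small intestine PI3 and LAMP1 each kept theirs in 13 of 14 settings, JUN in 12 and SIGLEC1 in 9, and LEPR kept its call at day 2 in 8 of 14. RXFP4 kept its call in the colon in 11 of 16 settings and TMPRSS15 in 10. At day 5 between the sites, fits of the compared groups alone ended every named call except that of PI3. The planned lists and the planned list alternatives were not run, since no list held 5 named genes. Spot intensities were not used here, so the dependence on signal over background is open.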

Other observations

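The adjustment over the 175 named genes alone and the comparison of the sexes were chosen after the data were seen. In the colon between day 0 and day 2, PI3 had a change of 0.38 ± 0.084 and RXFP4 one of 0.27 ± 0.069, with limma adjusted p of 0.158 and 0.251 over all features and 0.0175 and 0.0490 over the named genes alone. Both values had the sign of the change from day 0 to day 5. The LAMP1 difference between the sites by age had an adjusted p of 0.0176 over the named genes alone. Of genes known to mark the colon, KLF4 had a difference, colon minus small intestine, of 0.11 ± 0.037 at day 5 (adjusted p = 0.0503), and RXFP4 had a difference of -0.27 ± 0.072 at day 0 (adjusted p = 0.0671) and 0.01 ± 0.072 at day 5. The peptide transporter gene SLC15A1, known from the absorbing small intestine, had a difference of -0.02 ± 0.063 at day 5 (adjusted p = 0.847).

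Males and females differed past the threshold at few features. Unnamed spot 9480 was lower in males by a log2 difference of -0.69 ± 0.084 in the small intestine (adjusted p = 1.64e-05; 15 males and 21 females) and of -0.61 ± 0.078 in the colon (adjusted p = 0.000409; 12 males and 18 females). Spot 4715 was lower in males in the small intestine (-0.40 ± 0.047, adjusted p = 1.64e-05) and had -0.30 ± 0.071 in the colon (adjusted p = 0.149). Limma called these 2 features of 19798 in the small intestine and 1 of 19743 in the colon. At an unadjusted p under 0.05 there were 957 in the small intestine, against 989.9 expected by chance, and 3582 in the colon, against 987.15. No splits were run for sex, and a split for status in the colon at day 5 reached 5335 features. The first 2 components of the colon arrays also correlate with sex, at 0.326 and 0.407 in size. The colon count therefore does not show a broad difference between the sexes. The control group held 14 females and 4 males and the IUGR group 7 females and 11 males.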
